A study of Rattus norvegicus with 18 samples.

How the data were processed

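The series holds 18 bulk mRNA sequencing libraries from rat bone repairing around 3D-printed scaffolds. Per the labels, polyadenylated RNA was taken from cells released from the marrow and bone within 1 mm of the implant, after red blood cell lysis and collagenase digestion, and libraries were made with an Illumina mRNA kit. There are 6 groups of 3 libraries: 3 scaffolds at weeks 2 and 6. The labels do not say if libraries of a group came from separate animals. The spread between them, which gene p-values measure, may be technical in part.

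The authors deposited a table of read counts per gene for all libraries and a matching table of normalised values. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0, aligned with STAR 2.7.9a to build Rnor_6.0, and counted with featureCounts, for which no version is given beside that of Subread, 2.0.1. The annotation, strand setting and filters are not given in the sources used here. In the deposited count table the unit is the count of reads per gene symbol, not normalised. The normalised values deposited by the authors have the unit signal: each equals the count divided by a single size factor per library, checked over all genes, and they served only to read those factors. The tables name genes by symbol and give no coordinates. A reference table of assembly GRCr8 was used only to match gene names, and 14821 of the 17337 symbols were found in it.

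Total counts ran from 18880604 to 27186587 per library. No pair of libraries within a group was a duplicate: the lowest chi-square per degree of freedom between a pair was 30.5. At this depth counting error is small for abundant genes but not for those of few counts. The biological coefficient of variation from the common dispersion was 26.0%.

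Main tests used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 11814 genes holding 99.98% of all counts. Normalisation was TMM. The model had a term per group over all 18 libraries. The quasi-likelihood fit was robust (12 residual degrees of freedom, prior degrees of freedom 2.92). Log2 CPM used a prior count of 2. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. There were 12 comparisons: each pair of scaffolds at each week, week 6 against week 2 within each scaffold, and the change of each scaffold difference between the weeks (interaction).

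Gene groups were tested against other genes with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Before the data were examined, 40 lists were fixed for bone, marrow, immune and signalling functions, along with the comparisons, tests, other settings and the rule for named genes. Of 707 list entries, 645 matched a symbol in the table, 4 matched an older symbol, and 58 had no match. The 38 lists with at least 5 tested members were tested. The other 2, the sex-linked and the mitochondrially encoded lists, had too few: none of the 13 mitochondrial genes is in the table, Xist, Kdm5d, Uty and Usp9y are missing, Ddx3y had 0 to 6 counts per library, Eif2s3y 0 to 1 and Sry is listed at 0. Each list call was also made with the correlation estimated from the data. Each library has a list score, the mean over members of log2 CPM after centring each gene on all 18 libraries.

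Genes were named by rule: the largest changes past the threshold in each direction with log2 CPM of at least 1, a gene symbol that is not a placeholder and no overlap between the groups; a fixed panel of 19 bone, osteoclast and immune genes; and from each called list the members with the smallest p. Where no gene passed, the 5 with the smallest unadjusted p in that direction are given as such. RGD1562865 is the table's older symbol for Bach2. Values beside genes are mean CPM (counts scaled by edgeR to library size) ± SD over 3 libraries. A count of separated genes is of genes whose CPM ranges do not overlap between the groups.

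Tests were tried on data simulated for ACPC-NP against PCL at week 2. EdgeR recovered 51 of 100 genes changed 2-fold and 90 of 100 changed 4-fold, with 7 false calls among 11797. DESeq2 recovered 64 and 96 with 20 false calls, and voom with quality weights 49 and 87 with 7. With no gene changed, edgeR called 0 genes and camera 0 lists. Camera recovered 4 of 4 lists shifted 1.5-fold, at both correlations, with 0 false calls among 34 others.

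The other settings fixed in advance were DESeq2 1.42.0, voom with quality weights, the size factors of DESeq2 in edgeR, no low-count filter, only the groups compared, the replicate number as an added model term, an estimated correlation for the list tests, and each library left out in turn. Other splits of the same libraries into groups of the same sizes were counted. Chosen after seeing the data were ACPC-NP against the mean of CaP and PCL at each week, voom without replicate 3 of ACPC-NP at week 2, the shared spread estimated without that library, and list values without doubted libraries. Figures were drawn with matplotlib 3.10.9. No library was left out of the main results. Isoforms and variants were not analysed here, since the deposited tables hold gene totals.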

Results

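Gene expression was measured in rat cells freed from marrow and bone next to scaffolds that filled a critical-size defect of the radius. The scaffolds were printed polycaprolactone alone (PCL), PCL with calcium phosphate microparticles (CaP), and PCL with nanoparticles of amorphous calcium phosphate and chitosan (ACPC-NP). Tissue was taken at weeks 2 and 6, and each of the 6 groups of scaffold and week has 3 libraries. Of 11814 genes tested, 591 would reach an unadjusted p under 0.05 by chance. Differences between groups are log2 fold changes ± their standard error, the difference of a list is the median over its members, levels are mean CPM ± SD over 3 libraries, and adjusted p-values of genes are from edgeR.

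ACPC-NP week 2 replicate 3 stood apart from all other libraries. It lay at 91.4 on the first principal component, which held 26.1% of the variance, while the others lay between -23.9 and 25.5. Fth1, the heavy chain of the iron store ferritin, took 3.51% of its counts against 0.129% to 0.467% in the others. Its score on the immediate early list was 1.97, where the 6 CaP and PCL libraries of week 2 ranged from -0.717 to 0.207. Values without it stand beside the called lists that it moved most. Among the lists called at the preset correlation, median, mean and test had the same sign in every comparison, and 0 of 38 lists were called in any comparison with an estimated correlation.

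**Figure D1:**
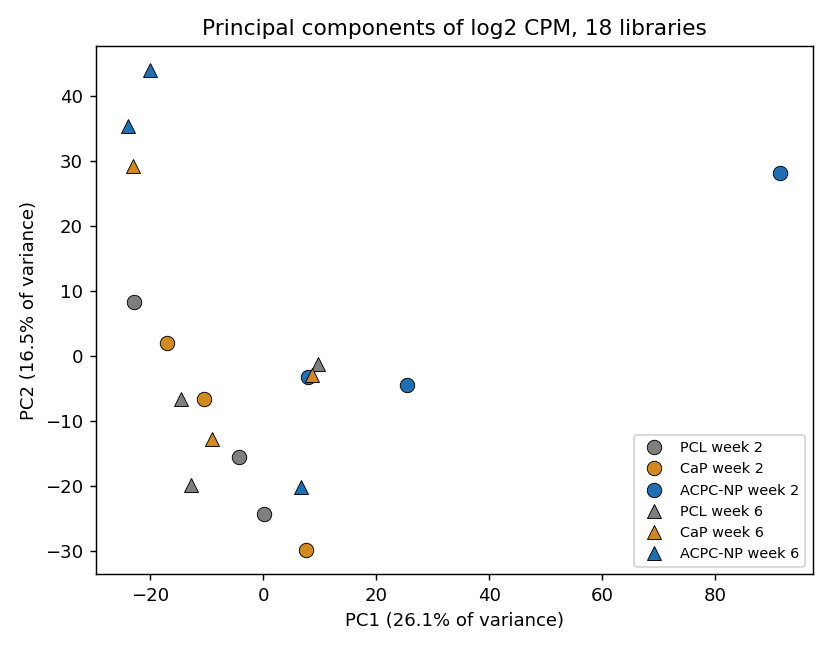
First against second principal component of the log2 CPM of all tested genes for the 18 libraries, with colour for the scaffold and marker for the week. ACPC-NP week 2 replicate 3 lies at 91.4 on the first component, and the other 17 libraries lie between -23.9 and 25.5.

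**Figure D2:**
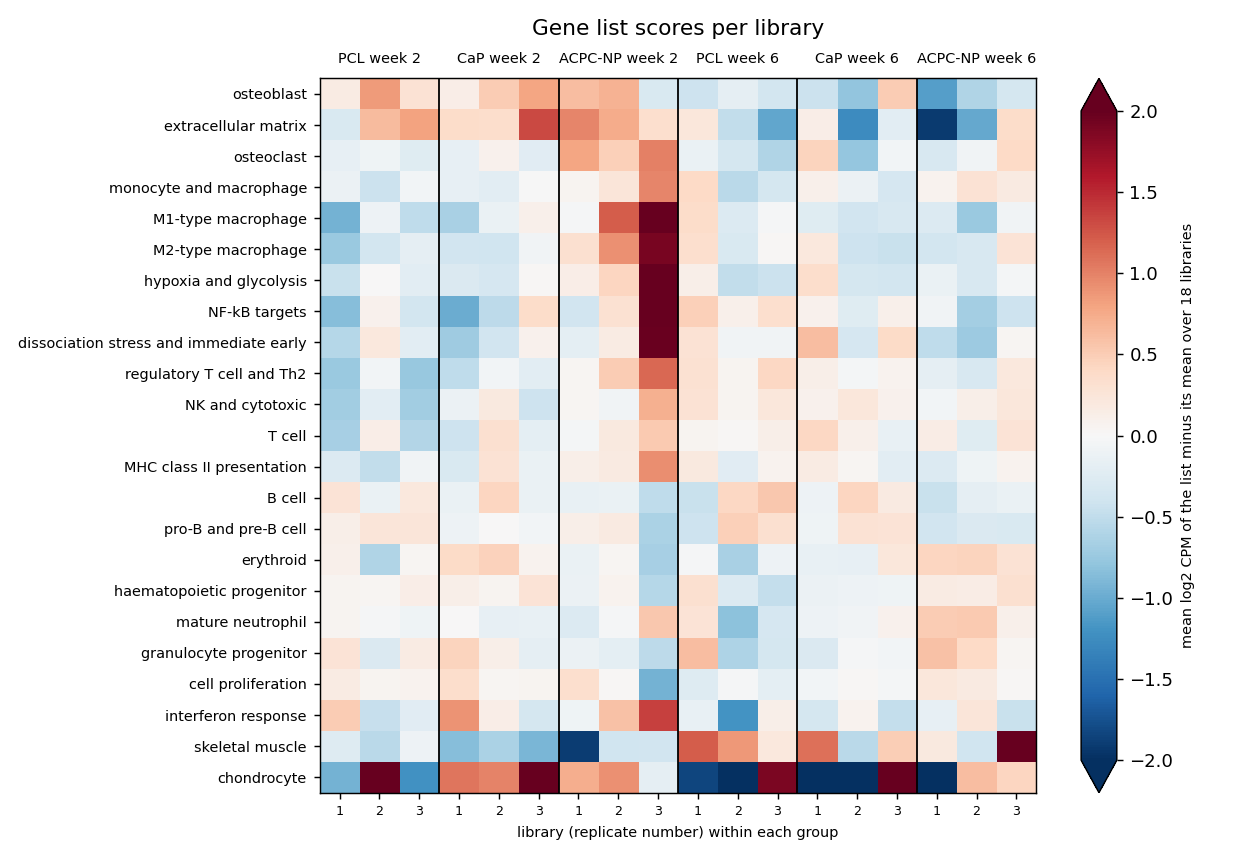
Scores of 23 gene lists (vertical) in the 18 libraries (horizontal), each the mean of centred log2 CPM over the members, with colour for the score. The osteoclast score lies between 0.471 and 1.01 in the ACPC-NP libraries of week 2, above every CaP and PCL library of that week.

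What the nanoparticles add to PCL early in repair was read from ACPC-NP against PCL at week 2. The osteoclast list rose around ACPC-NP, with 12 of 14 members above 0 and a median log2 difference of 0.91 (camera adjusted p = 1.96e-07; adjusted p = 0.238 with an estimated correlation). Of these members 11 were higher adjusted over the list alone and 0 over all genes. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, stood at 309 ± 88.3 CPM against 144 ± 22.6, a difference of 1.10 ± 0.29 (adjusted p = 0.0914). Nfatc1, the transcription factor that drives osteoclast formation, stood at 97.7 ± 11.5 against 66.8 ± 2.23. Ctsk, the collagenase of the resorption pit, stood at 446 ± 155 against 122 ± 67.5, a difference of 1.86 ± 0.63. Spp1, osteopontin of the osteoblast list, stood at 2709 ± 441 against 495 ± 243, a difference of 2.45 ± 0.61 that was 2.56 without replicate 3. The osteoclast list kept its call without replicate 3, at a median of 0.47 (adjusted p = 5.71e-09).

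Macrophage and glycolysis lists moved the same way in this comparison. The M1-type macrophage list rose with 16 of 17 members above 0 and a median of 2.45 (camera adjusted p = 1.04e-10; adjusted p = 0.238 with an estimated correlation), and 13 were higher adjusted over the list alone. Il1b stood at 3717 ± 5017 against 412 ± 164 CPM, a difference of 3.17 ± 0.83 that was 0.99 without replicate 3. Nos2, the inducible nitric oxide synthase, differed by 3.43 ± 0.90, or 1.24 without that library. The M2-type list rose with 15 of 17 above 0 and a median of 1.13 (adjusted p = 9.08e-09; adjusted p = 0.238 with an estimated correlation), and 11 were higher adjusted over the list alone. Arg1, which breaks down arginine, stood at 579 ± 836 against 3.51 ± 2.06, a difference of 7.36 ± 1.35 that was 4.80 without replicate 3. Il1rn, the interleukin 1 receptor antagonist, differed by 4.26 ± 0.81, or 2.31 without it. The hypoxia and glycolysis list rose with 23 of 23 members above 0 and a median of 1.52 (adjusted p = 6.39e-12; adjusted p = 0.378 with an estimated correlation), 19 of them adjusted over the list alone. Slc2a1, a glucose transporter, stood at 973 ± 1331 against 64.5 ± 24.6, a difference that was 1.68 without replicate 3. The general monocyte and macrophage list rose by a median of 0.86 (adjusted p = 0.00015; adjusted p = 0.591 with an estimated correlation), with Cd68 at 421 ± 211 against 161 ± 11.0 and a difference of 0.88 without replicate 3. Without replicate 3 the medians were 0.90, 0.45, 0.41 and 0.53 for the M1-type, M2-type, hypoxia and monocyte lists, and all 4 stayed called.

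The NF-kB target list rose by a median of 1.92 with 15 of 16 members above 0 (adjusted p = 8.31e-07; adjusted p = 0.597 with an estimated correlation), which was 0.15 without replicate 3 (adjusted p = 0.00894). The immediate early list, which also reads stress during tissue digestion, rose by 0.85 (adjusted p = 2.28e-05; adjusted p = 0.609 with an estimated correlation), and the call ended without replicate 3 at 0.01 (adjusted p = 0.635). The T cell list rose by a median of 0.71 (adjusted p = 9.12e-05; adjusted p = 0.591 with an estimated correlation) and the NK and cytotoxic list by 0.63 (adjusted p = 0.00015; adjusted p = 0.247 with an estimated correlation). Prf1, the pore-forming perforin, stood at 10.8 ± 6.52 against 3.00 ± 0.513 CPM, a difference of 1.84 that was 1.22 without replicate 3. The regulatory T cell and Th2 list rose by 1.01 (adjusted p = 0.000415; adjusted p = 0.238 with an estimated correlation), and Foxp3, the factor that defines regulatory T cells, differed by 1.91 ± 0.31 (adjusted p = 0.0712). The MHC class II list rose by a median of 0.71 with 9 of 9 members above 0 (adjusted p = 2.28e-05; adjusted p = 0.334 with an estimated correlation). The interferon response list rose by 0.31 (adjusted p = 0.0101; adjusted p = 0.707 with an estimated correlation), a call that ended without replicate 3 (adjusted p = 0.227). The regulatory T cell and MHC class II lists were at 0.49 and 0.30 without it, and both stayed called.

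The B cell list fell by 0.48 at the median with 12 of 13 members below 0 (adjusted p = 0.000501; adjusted p = 0.609 with an estimated correlation). Ebf1, a factor of early B cell development, stood at 174 ± 30.5 against 285 ± 38.9 CPM. Skeletal muscle (median -0.47), ribosomal protein (-0.10), eosinophil and mast cell (-0.32), pro-B (-0.30), granulocyte progenitor (-0.46) and proliferation (-0.20) lists also fell, with adjusted p from 0.00015 to 0.0358, and adjusted p from 0.609 to 0.742 with an estimated correlation. The last 4 of these lost their calls without replicate 3, with adjusted p of 0.229, 0.848, 0.142 and 0.142 and medians of -0.10, -0.06, -0.30 and 0.08, and muscle was at -0.80. Among osteoblast genes Runx2, the factor of osteoblast fate, was at 40.0 ± 1.10 against 36.7 ± 2.06, Col1a1 at 16306 ± 7602 against 18847 ± 4358 and Bglap, osteocalcin, at 309 ± 123 against 361 ± 108. Sp7 differed by -0.48 ± 0.41, Alpl by -0.48 ± 0.27 and Ibsp by -0.24 ± 0.66, while Spp1 rose. Their list was not called (median -0.24, adjusted p = 0.390). The chondrocyte list was not called either (median -1.45, adjusted p = 0.342), and its sign rests on PCL replicate 2: without that library the median was 2.02 with 14 of 14 members above 0 (adjusted p = 0.0245), and without PCL replicates 1 and 3 it was -1.99 and -1.97 (adjusted p = 0.0242 and 0.0360). Other panel genes were Il6 at 3.88 ± 0.99, Il10 at 4.47 ± 0.90, Mrc1 at 1.18 ± 0.39, Vegfa at 1.76 ± 0.65, Tgfb1 at 0.17 ± 0.19 and Bmp2 at 0.20 ± 0.64. Without replicate 3 the first 4 were at 1.22, 2.16, 0.45 and 0.16. Tnf was listed at 0 in every library.

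In this comparison edgeR called 0 of 11814 genes over all genes, with 1854 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0712. By the naming rule the smallest unadjusted p belonged to Gal, Foxp3, Ccl4, Cxcl3 and Car4 among higher genes and to Padi3, Trmt10a, Mccc1, Rom1 and Camk2b among lower ones. Gal, the neuropeptide galanin, stood at 11.0 ± 5.26 against 1.05 ± 0.251 CPM, and Padi3 at 44.6 ± 6.09 against 76.1 ± 3.70. DESeq2 called 603 genes higher and 29 lower, and voom with quality weights 270 and 39. The edgeR count was 877 without ACPC-NP week 2 replicate 1, 383 without replicate 2 and 0 without replicate 3. Of the 19 list calls, 11 held with each library left out in turn: osteoclast, monocyte, M1-type, M2-type, hypoxia, NF-kB, MHC class II, T cell, NK, regulatory T cell and B cell. The T cell median was 1.13 without PCL replicate 2 and 0.42 without replicate 3, the regulatory T cell median 0.58 without PCL replicate 1 and 1.82 without replicate 2, and the muscle call ended without ACPC-NP replicate 1 at -0.14 (adjusted p = 0.566). Ranges did not overlap between the groups for 17.0% of genes, where chance gives 10%.

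**Figure D3:**
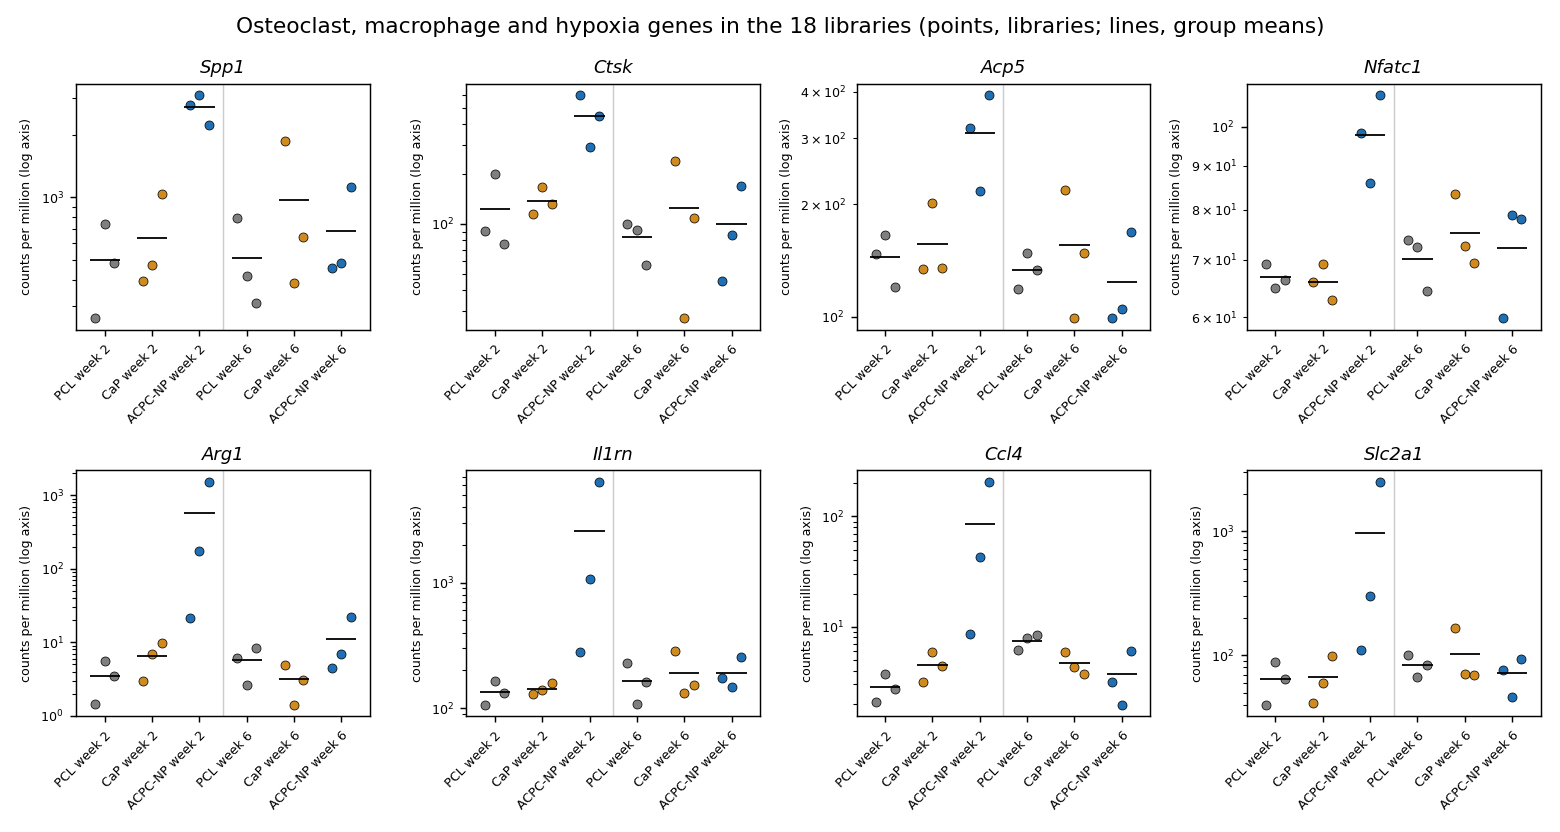
CPM on a log axis of Spp1, Ctsk, Acp5, Nfatc1, Arg1, Il1rn, Ccl4 and Slc2a1 in each library, with points for libraries and lines for group means. At week 2 Spp1 averages 2709 around ACPC-NP, 635 around CaP and 495 around PCL.

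ACPC-NP and CaP differ in chitosan, in particle size and in the mineral itself, and these were not varied apart. They were compared at week 2 first. The osteoclast list rose by a median of 0.90 with 12 of 14 members above 0 (camera adjusted p = 1.49e-07; adjusted p = 0.505 with an estimated correlation), 10 of them adjusted over the list alone. Siglec15, a receptor of differentiating osteoclasts, stood at 4.28 ± 1.35 against 0.862 ± 0.416 CPM, and Nfatc1 differed by 0.57 ± 0.12. Acp5 differed by 0.98 ± 0.29 and Ctsk by 1.69 ± 0.63. The M1-type list rose by 2.28 and the M2-type list by 1.19 (both adjusted p = 8.66e-08; adjusted p = 0.508 and 0.505 with an estimated correlation), each with 10 members higher adjusted over the list alone. Arg1 differed by 6.46 ± 1.28 and by 3.90 without replicate 3, Il1rn by 4.18 ± 0.81 and by 2.23 without it. Cd274, the checkpoint ligand PD-L1, stood at 122 ± 173 against 3.29 ± 0.920, a difference of 5.22 that was 2.79 without it. The hypoxia list rose by 1.47 with 22 of 23 above 0 (adjusted p = 3.27e-12; adjusted p = 0.508 with an estimated correlation), and Egln3, an oxygen sensor, differed by 3.00 ± 0.67, or 0.96 without it. The monocyte and macrophage list rose by 0.67 (adjusted p = 0.000581; adjusted p = 0.564 with an estimated correlation), with Cd68 at 421 ± 211 against 148 ± 19.4.

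The NF-kB target list rose by 1.78 (adjusted p = 1.48e-07) and the immediate early list by 1.00 in 21 of 21 members (adjusted p = 1.02e-07), each with adjusted p = 0.564 with an estimated correlation. Hspa1b, a heat shock protein, stood at 41.3 ± 57.0 CPM around ACPC-NP, a difference of 3.93 ± 0.94 (adjusted p = 0.105) that was 1.63 without replicate 3. The regulatory T cell and Th2 list rose by 0.83 (adjusted p = 0.0176) and MHC class II by 0.26 (adjusted p = 0.00683), each again with adjusted p = 0.564 with an estimated correlation. The erythroid list fell by 0.59 at the median with 14 of 15 below 0 (adjusted p = 1.48e-07; adjusted p = 0.508 with an estimated correlation). Klf1, the master factor of red cell formation, stood at 172 ± 65.1 against 280.5 ± 38.2, a difference of -0.71 that was -0.46 without replicate 3. The eosinophil and mast cell list fell by 0.46 (adjusted p = 0.00352; adjusted p = 0.564 with an estimated correlation), with Prg2, a granule protein, at 1880.1 ± 598 against 3265 ± 540.4. Proliferation (median -0.25), B cell (-0.28), granulocyte progenitor (-0.53) and ribosomal protein (-0.12) lists fell with adjusted p from 2.2e-05 to 0.0176, and adjusted p of 0.726 to 0.848 with an estimated correlation. Osteoblast (median -0.17, adjusted p = 0.362) and chondrocyte (-0.96, adjusted p = 0.119) lists were not called. Runx2 differed by -0.06 ± 0.14, Col1a1 by -0.17 ± 0.40 and Spp1 by 2.09 ± 0.60 (adjusted p = 0.127). Without replicate 3 osteoclast, M1-type, M2-type, hypoxia and erythroid lists stayed called at medians of 0.48, 0.57, 0.46, 0.43 and -0.40, as did monocyte, NF-kB and immediate early lists at 0.42, 0.15 and 0.20. The calls of the granulocyte progenitor, eosinophil, B cell, MHC class II and proliferation lists ended, with adjusted p of 0.0753, 0.0965, 0.109, 0.287 and 0.568, the last 2 at medians of 0.01 and 0.03. The 8 lists that stayed called at the medians above held with each library left out in turn, while the regulatory T cell and ribosomal calls ended without ACPC-NP replicate 2 and without CaP replicate 1 (regulatory T cell 0.52, adjusted p = 0.0742), and the B cell call ended without CaP replicate 2 at -0.12 (adjusted p = 0.293).

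EdgeR called 0 genes against CaP, with 1858 at an unadjusted p under 0.05. Car4, F3, Cd274, Msr1 and Ccl4 had the smallest unadjusted p among higher genes and Spef1, Fam98c, Wdr45, Ppp1r13b and Slc22a3 among lower ones (smallest adjusted p = 0.1005). F3, tissue factor, which starts coagulation, differed by 5.38 ± 0.94 and by 2.97 without replicate 3. DESeq2 called 537 genes higher and 58 lower, and voom 289 and 87. The edgeR count was 893 without ACPC-NP week 2 replicate 1, 141 without replicate 2 and 0 without replicate 3, and 16.5% of genes had separate ranges where chance gives 10%.

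A comparison of ACPC-NP with the mean of CaP and PCL at week 2, chosen after seeing the data, set 3 libraries against 6. EdgeR called 577 genes higher and 13 lower, and 10 without replicate 3. Spp1 rose by 2.27 ± 0.48, at 2709 ± 441 against 565 ± 281 CPM (adjusted p = 0.0194). In the osteoclast list 7 of 14 members rose: Acp5 by 1.04 ± 0.24, Nfatc1 by 0.56 ± 0.10, Oscar, Clcn7, Tcirg1, Itgb3 and Siglec15. Among M2-type genes 7 of 17 rose, with Arg1 by 6.91 ± 0.97, Il10, an anti-inflammatory cytokine, by 4.25 ± 0.67 and Mrc1, the mannose receptor, by 1.19 ± 0.32. Among M1-type genes 11 of 17 rose, among hypoxia genes 15 of 23 and among NF-kB targets 8 of 16. Il2ra rose by 2.01 ± 0.40. Foxp3 was called at 1.21 ± 0.25, an average of 1.91 against PCL and 0.51 ± 0.29 against CaP (adjusted p = 0.430), and rests mainly on PCL. Mmp14, a membrane protease that cleaves collagen, rose by 2.53 ± 0.53. The 13 lower genes included Slc22a3 (-1.57 ± 0.41), Dtx3 (-0.71 ± 0.18) and Padi3 (-0.57 ± 0.15). Of the genes named here only Arg1 stayed called without replicate 3. Spp1 was then no smaller, at 2.38 ± 0.54 (adjusted p = 0.152). Il10, Mrc1, Mmp14, Il2ra and Foxp3 were at 1.95, 0.46, 1.91, 1.44 and 0.92, and Acp5, Nfatc1, Slc22a3, Dtx3 and Padi3 at 0.83, 0.46, -1.32, -0.66 and -0.48.

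The 10 genes called without ACPC-NP week 2 replicate 3 were all higher: F3, Cd274, Car4, Cxcl3, Fcgr2b, Ccl4, Arg1, Irg1, Gal and Il1rn, with adjusted p from 0.0190 to 0.0485. Car4, a membrane-bound carbonic anhydrase, was then higher by 7.34 and Arg1 by 4.35. The pooled count was 1363 without ACPC-NP replicate 1 and 930 without replicate 2. It was 182 and 195 without CaP replicates 1 and 2, and 172, 385 and 271 without PCL replicates 1, 2 and 3. Separate ranges held for 8.34% of genes, where chance gives 2.38%.

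CaP against PCL at week 2 sets the microparticles against the polymer alone, with few genes at a small p. The erythroid list rose by a median of 0.43 with 15 of 15 members above 0 (camera adjusted p = 4.31e-10; adjusted p = 0.439 with an estimated correlation). Tfrc, the transferrin receptor, stood at 1095 ± 101 against 846 ± 127 CPM. The NK and cytotoxic list rose by 0.49 with 11 of 12 above 0 (adjusted p = 5.68e-06; adjusted p = 0.439 with an estimated correlation), with Prf1 at 6.13 ± 1.72 against 3.00 ± 0.513. The T cell list rose by 0.34 (adjusted p = 0.000243; adjusted p = 0.904 with an estimated correlation). Foxp3 had the smallest unadjusted p, at 2.43 ± 0.795 against 0.921 ± 0.205, a difference of 1.40 ± 0.31. M1-type (median 0.30), MHC class II (0.25) and interferon response (0.33) lists rose with adjusted p from 0.0161 to 0.0337, while muscle (-0.56) and pro-B (-0.19) lists fell with adjusted p of 0.000549 and 0.000255. With an estimated correlation their adjusted p lay between 0.904 and 0.978. Runx2 differed by 0.19 ± 0.14, Col1a1 by -0.04 ± 0.40, Spp1 by 0.36 ± 0.58 and Arg1 by 0.90 ± 1.11. EdgeR called 0 genes, with 183 at an unadjusted p under 0.05, below the 591 of chance, DESeq2 and voom called 0, and 6.02% of genes had separate ranges where chance gives 10%. The 8 called lists became 13 without CaP week 2 replicate 1 and 13 without PCL week 2 replicate 2. Only the erythroid, pro-B and muscle calls held with each library left out in turn, with the erythroid list at 0.24 without PCL replicate 2. Without CaP replicate 2 the NK, T cell and MHC class II calls ended at 0.10, 0.05 and 0.05 (adjusted p = 0.108, 0.622 and 0.949). Interferon was at -0.10 without CaP replicate 1 (adjusted p = 0.384) and M1-type at 0.07 without CaP replicate 3 (adjusted p = 0.255).

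At week 6 ACPC-NP against PCL asks what the nanoparticles add later in repair. The erythroid list rose by a median of 0.74 with 14 of 15 members above 0 (camera adjusted p = 7.38e-07; adjusted p = 0.812 with an estimated correlation), 11 of them adjusted over the list alone and 0 over all genes. Car1, the carbonic anhydrase of red cells, stood at 445 ± 64.2 against 179 ± 34.9 CPM, a difference of 1.31 ± 0.37. Hbb, a haemoglobin beta chain, stood at 50186 ± 7982 against 27109 ± 6925, and Slc4a1, the anion exchanger of the red cell membrane, at 6192 ± 821 against 3666 ± 711. Neutrophil genes rose by a median of 0.51 with 14 of 14 members above 0 (adjusted p = 7.09e-05), with Lcn2, an iron-binding granule protein, at 1397 ± 264 against 436 ± 337. Granulocyte progenitor (0.36), haematopoietic progenitor (0.30) and monocyte and macrophage (0.33) lists rose with adjusted p from 0.0233 to 0.0452. Cd163, the haemoglobin scavenger receptor of macrophages, stood at 116 ± 50.0 against 47.4 ± 21.6. These lists had adjusted p = 0.812 with an estimated correlation.

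The B cell list fell by 0.64 at the median with 11 of 13 below 0 (adjusted p = 0.00505) and the pro-B list fell by 0.51 (adjusted p = 0.00884), with 4 and 5 members lower adjusted over the list alone. Ebf1 stood at 152 ± 15.0 against 292 ± 112 CPM, Spib at 694 ± 113 against 1318 ± 559 and RGD1562865 (Bach2) at 133 ± 18.5 against 306 ± 114. The NF-kB target list fell by 0.80 with 15 of 16 below 0 (adjusted p = 0.00884), with Nfkbie, an inhibitor of NF-kB, at 127 ± 21.0 against 262 ± 61.3. The BMP and TGF-beta list fell by 0.35 (adjusted p = 0.0189), with Id3, a target of BMP signals, at 55.9 ± 14.6 against 168 ± 45.1 and Smad7, a brake on TGF-beta signals, at 94.7 ± 16.9 against 229 ± 37.4. Proliferation (0.26, adjusted p = 0.002) and oxidative phosphorylation (0.18, adjusted p = 0.000384) lists rose with 25 of 26 members above 0 each. Each of these calls had adjusted p = 0.812 with an estimated correlation. Osteoblast values were lower without a call (median -0.51, adjusted p = 0.435), with Col1a1 at 5825 ± 1566 against 8305 ± 1567 and Bglap at 139 ± 30.8 against 226 ± 60.8. Sp7 differed by -0.84 ± 0.43, Alpl by 0.42 ± 0.27, Spp1 by 0.44 ± 0.58, Acp5 by -0.10 ± 0.29 and Arg1 by 0.97 ± 1.08 (-0.01 without ACPC-NP replicate 3). The muscle list stood at 0.74 (adjusted p = 0.348) and at -0.97 without ACPC-NP week 6 replicate 3, where it was called lower (adjusted p = 0.00135). It was called higher without replicates 1 and 2, at 1.15 and 1.20 (adjusted p = 0.0183 and 0.00126).

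EdgeR called 0 genes at week 6 against PCL, with 2588 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0783. March2, Fntb, Tusc2, F2rl1 and Slc46a3 led the higher genes and Wnt10b, Apc, Mapk8, Hivep3 and Prkci the lower ones. Wnt10b, a ligand that favours bone formation, stood at 3.27 ± 0.837 against 13.0 ± 5.92 CPM, a difference of -1.99 ± 0.33. March2, a ubiquitin ligase, stood at 318 ± 19.6 against 176 ± 27.8. DESeq2 called 379 genes higher and 499 lower, and voom 1974 and 2082. Without PCL week 6 replicate 1, which had a voom quality weight of 0.240, edgeR called 688 higher and 1099 lower; Wnt10b was then at -2.27 (adjusted p = 0.0029) and March2 at 0.95 (adjusted p = 0.0053). The NF-kB (adjusted p = 0.0878), BMP and TGF-beta (adjusted p = 0.0715) and proliferation (adjusted p = 0.0715) calls ended without that library, and the 11 called lists became 18 without ACPC-NP week 6 replicate 3. Only the neutrophil, erythroid and oxidative phosphorylation calls held with each library left out in turn, with neutrophils at 0.90 without PCL replicate 1 and 0.27 without replicate 2. Without PCL replicate 1 the B cell, pro-B, granulocyte progenitor, haematopoietic progenitor and monocyte lists were at -0.97, -0.80, 1.02, 0.68 and 0.65. The B cell and haematopoietic progenitor calls ended without PCL replicate 3 at -0.38 and 0.17 (adjusted p = 0.0666 and 0.145), and the pro-B, granulocyte progenitor and monocyte calls without PCL replicate 2 at -0.27, 0.10 and 0.11 (adjusted p = 0.0679, 0.209 and 0.292). Ranges were separate for 27.0% of genes, where chance gives 10%.

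**Figure D4:**
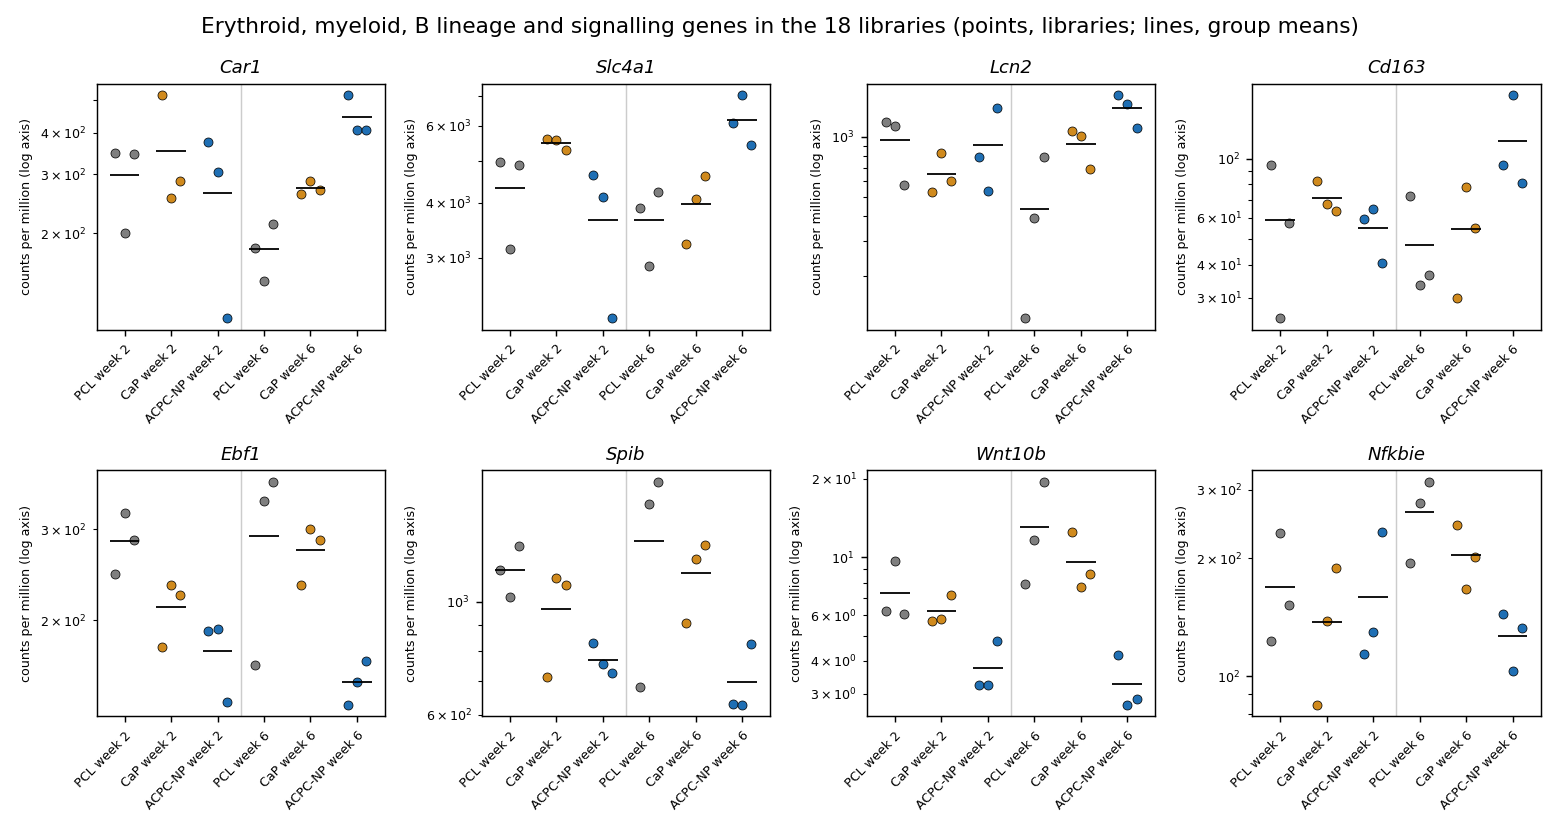
CPM on a log axis of Car1, Slc4a1, Lcn2, Cd163, Ebf1, Spib, Wnt10b and Nfkbie in each library, with points for libraries and lines for group means. At week 6 Slc4a1 averages 6192 around ACPC-NP and 3666 around PCL, and Wnt10b 3.27 and 13.0.

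ACPC-NP against CaP at week 6 compares the 2 mineral scaffolds, which also differ in chitosan, in later repair. The erythroid list rose by a median of 0.55 with 14 of 15 above 0 (camera adjusted p = 5.08e-07; adjusted p = 0.659 with an estimated correlation), with Hbb at 50186 ± 7982 against 26709 ± 4657 CPM and Alas2, which starts haem synthesis in red cells, at 3236 ± 565 against 1884 ± 395. Neutrophil genes rose by 0.46 with 14 of 14 members above 0 (adjusted p = 0.000166; adjusted p = 0.659 with an estimated correlation), with S100a8, a calcium-binding alarm protein, at 8866 ± 1801 against 5461 ± 1087. The megakaryocyte list rose by 0.70 with 6 of 6 members above 0 (adjusted p = 0.00345; adjusted p = 0.659 with an estimated correlation). The B cell list fell by 0.50 and the pro-B list fell by 0.53 (both adjusted p = 4.07e-05; both adjusted p = 0.659 with an estimated correlation), with Ebf1 at 152 ± 15.0 against 273 ± 35.1. The osteoblast list fell by 0.62 with 13 of 15 below 0 (adjusted p = 0.0213; adjusted p = 0.893 with an estimated correlation). Bglap differed by -0.89 ± 0.42, Ibsp by -1.25 ± 0.67 and Col1a1 by -0.62 ± 0.41, while Phospho1, which frees phosphate for mineral, stood at 189.8 ± 24.1 against 128 ± 30.8. The matrix list fell by 0.27 with 17 of 18 below 0 (adjusted p = 0.0405; adjusted p = 0.907 with an estimated correlation), with Lox, the collagen cross-linking enzyme, at 5.02 ± 2.45 against 10.9 ± 5.57. The osteoblast call rests on CaP replicate 3, without which the list was at -0.05 (adjusted p = 0.981), and it also ended without ACPC-NP replicate 1 at -0.43 (adjusted p = 0.255). Without CaP replicate 1 the megakaryocyte call ended at 0.51 (adjusted p = 0.112) and the matrix list turned to 0.10 (adjusted p = 0.682). The matrix call also ended without ACPC-NP replicates 1 and 2 and CaP replicate 3, at 0.09, -0.04 and -0.21 (adjusted p = 0.876, 0.168 and 0.144), and the list was at -0.56 without CaP replicate 2.

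The immediate early list fell by 0.53 with 20 of 21 below 0 (adjusted p = 4.07e-05; adjusted p = 0.82 with an estimated correlation), with Nr4a1 at 168 ± 33.1 against 386 ± 174 CPM. The BMP and TGF-beta list fell by 0.28 (adjusted p = 0.00799; adjusted p = 0.82 with an estimated correlation) and NF-kB targets fell by 0.43 (adjusted p = 0.0218; adjusted p = 0.907 with an estimated correlation). The adipocyte list rose by 0.56 (adjusted p = 0.0183; adjusted p = 0.659 with an estimated correlation), with Pparg, the master factor of fat cells, at 8.30 ± 1.65 against 5.22 ± 0.185. Granulocyte progenitor (0.60), haematopoietic progenitor (0.35), monocyte and macrophage (0.26), oxidative phosphorylation (0.17), proliferation (0.16) and ribosomal protein (0.07) lists rose with adjusted p from 0.000157 to 0.0499, and adjusted p from 0.659 to 0.907 with an estimated correlation. The muscle list rose by 1.06 with 16 of 16 members above 0 (adjusted p = 0.00799; adjusted p = 0.907 with an estimated correlation) and turned to -0.68 (adjusted p = 0.0123) without ACPC-NP week 6 replicate 3. Without that library the adipocyte, NF-kB and ribosomal calls ended (adjusted p of 0.0985, 0.0985 and 0.174), and the matrix and osteoblast lists were at -1.14 and -0.96 (adjusted p = 4.93e-07 and 0.0114). Without CaP replicate 3 the BMP and monocyte calls ended at -0.13 and 0.19 (adjusted p = 0.0685 and 0.275), and without CaP replicate 2 the muscle call ended at 0.73 (adjusted p = 0.318). Runx2 differed by -0.02 ± 0.14, Spp1 by -0.49 ± 0.58, Acp5 by -0.33 ± 0.29 and Arg1 by 1.81 ± 1.12 (0.83 without that library). Of the 18 list calls, 8 held with each library left out in turn: erythroid, neutrophil, granulocyte progenitor, haematopoietic progenitor, B cell, pro-B, oxidative phosphorylation and immediate early.

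EdgeR called 0 genes, with 1104 at an unadjusted p under 0.05 and a smallest adjusted p of 0.506; DESeq2 called 12 higher and 11 lower, and voom 15 and 56. With only the 2 groups compared edgeR called 1. March2, Lepr, Tusc2, Chp1 and Map4k5 led the higher genes and Spata5, Pianp, Wnt10b, Arhgap17 and Hivep3 the lower ones. Lepr, the leptin receptor, stood at 4.62 ± 0.380 against 1.27 ± 0.374 CPM and Wnt10b at 3.27 ± 0.837 against 9.61 ± 2.53. Separate ranges held for 24.9% of genes, where chance gives 10%.

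CaP against PCL at week 6 differed in few lists. The Schwann cell list fell by 0.48 at the median with 10 of 11 below 0 (camera adjusted p = 0.000574; adjusted p = 0.997 with an estimated correlation). The endothelial list fell by 0.36 (adjusted p = 0.0187), the osteoclast list rose by 0.19 with 12 of 14 above 0 (adjusted p = 0.0276), and proliferation (0.10) and neutrophil (0.08) lists rose (adjusted p of 0.0129 and 0.0464), each with adjusted p = 0.997 with an estimated correlation. Il20rb, a cytokine receptor chain, stood at 10.5 ± 6.26 against 2.63 ± 0.981 and Wnt5a at 6.82 ± 4.58 against 1.55 ± 0.793. Cldn12, at 15.7 ± 1.38 against 22.6 ± 2.46, had the smallest p of the lower genes, and Sepp1, the plasma selenium carrier, stood at 132 ± 7.08 against 213 ± 22.0. Runx2 differed by 0.21 ± 0.14, Col1a1 by 0.11 ± 0.40 and Spp1 by 0.93 ± 0.59. EdgeR called 0 genes, with 304 at an unadjusted p under 0.05, below the 591 of chance, and DESeq2 and voom called 0; 8.90% of genes had separate ranges where chance gives 10%. Without PCL week 6 replicate 1 edgeR called 1 gene, the endothelial and proliferation calls ended (adjusted p of 0.512 and 0.292) and 12 lists were called; the 5 lists became 11 and 8 without CaP replicates 1 and 3, and 11 and 8 without PCL replicates 2 and 3. Only the Schwann cell call held with each library left out in turn, at -0.24 without PCL replicate 2. The osteoclast list was at 0.05 without CaP replicate 1 (adjusted p = 0.839) and the neutrophil list at -0.17 without PCL replicate 2 (adjusted p = 0.439).

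Week 6 against week 2 within ACPC-NP follows repair over time around 1 scaffold. Gal fell from 11.0 ± 5.26 to 0.571 ± 0.146 CPM, a change of -4.25 ± 0.56, and was the only gene called (edgeR adjusted p = 0.0221). The call ended without ACPC-NP week 2 replicate 3, without any 1 library of week 6, with the replicate block (adjusted p = 0.0949) and with only the 2 groups compared (adjusted p = 0.308). The change was -3.82 without that week 2 library, and 1 other of the 10 splits also called 1 gene. The matrix list fell by 1.19 with 18 of 18 members below 0 (camera adjusted p = 3.74e-09; adjusted p = 0.313 with an estimated correlation), with Col1a1 at 5825 ± 1566 after 16306 ± 7602 and Lox at 5.02 ± 2.45 after 26.2 ± 11.8. The osteoblast list fell by 1.25 (adjusted p = 2.55e-05; adjusted p = 0.344 with an estimated correlation) with 9 members lower adjusted over the list alone, the osteocyte list fell by 1.36 (adjusted p = 0.0022; adjusted p = 0.313 with an estimated correlation) and the osteoclast list fell by 0.77 (adjusted p = 0.00077; adjusted p = 0.313 with an estimated correlation). Spp1 was at 686 ± 379 after 2709 ± 441 and Acp5 at 124 ± 38.8 after 309 ± 88.3. The M1-type list fell by 2.53 and the M2-type list fell by 1.07 (adjusted p of 5.51e-07 and 1.11e-05; both adjusted p = 0.313 with an estimated correlation), hypoxia genes fell by 1.32 (adjusted p = 1.69e-08; adjusted p = 0.383 with an estimated correlation) and NF-kB targets fell by 1.75 (adjusted p = 1.97e-06; adjusted p = 0.393 with an estimated correlation). Without ACPC-NP week 2 replicate 3 these 4 lists stayed called at -0.62, -0.62, -0.34 and -0.23, and the osteoclast list at -0.29.

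Erythroid (median 0.74, adjusted p = 1.08e-09), muscle (2.48, adjusted p = 1.19e-10) and eosinophil (0.75, adjusted p = 1.11e-05) lists rose around ACPC-NP, each with adjusted p = 0.313 with an estimated correlation. Neutrophil (0.62), granulocyte progenitor (0.60), progenitor (0.45), adipocyte (0.40), proliferation (0.25) and ribosomal protein (0.11) lists also rose, and immediate early (-0.97), interferon (-0.54), BMP and TGF-beta (-0.52) and MHC class II (-0.45) lists fell. Their adjusted p lay between 1.97e-06 and 0.0163, and their adjusted p between 0.313 and 0.828 with an estimated correlation. Camp, a neutrophil granule peptide, stood at 2784 ± 369 after 1510.3 ± 10.3 CPM. Without ACPC-NP week 2 replicate 3 the adipocyte, progenitor, MHC class II, interferon, proliferation and immediate early calls ended, with adjusted p from 0.052 to 0.761, while erythroid and BMP lists stayed called at 0.48 and -0.26. Muscle was at 0.73 without ACPC-NP week 6 replicate 3 (adjusted p = 0.000127), and the matrix list at -2.25 without it and -0.75 without week 6 replicate 1. The neutrophil call ended without week 2 replicate 1 (adjusted p = 0.128).

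Of all genes 2340 had an unadjusted p under 0.05; DESeq2 called 277 higher and 515 lower, and voom 623 and 764. The edgeR count was 882 without ACPC-NP week 2 replicate 1, 4 without replicate 2, and 0 without replicate 3 or any 1 library of week 6. Of the 21 list calls, 13 held with each library left out in turn, among them osteoblast, osteocyte, osteoclast, matrix, erythroid, M1-type, M2-type and hypoxia. Ranges were separate for 18.5% of genes, where chance gives 10%.

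Within CaP, week 6 against week 2, the matrix list fell by 1.09 at the median with 16 of 18 below 0 (camera adjusted p = 1.46e-09; adjusted p = 0.593 with an estimated correlation). Thbs2, a matrix protein that limits vessel growth, stood at 6.12 ± 4.20 after 33.5 ± 19.7 CPM and Col1a1 at 8935 ± 4026 after 18300.1 ± 7207. Osteoblast (-0.66) and osteocyte (-0.76) lists fell with adjusted p of 2.91e-06 and 0.00614, and muscle rose by 1.37 with 16 of 16 members above 0 (adjusted p = 3.59e-10), each with adjusted p = 0.593 with an estimated correlation. Erythroid genes fell by 0.40 with 14 of 15 below 0 (adjusted p = 2.93e-05; adjusted p = 0.658 with an estimated correlation) and endothelial genes fell by 0.61 (adjusted p = 0.00433; adjusted p = 0.788 with an estimated correlation). Interferon (-0.49), chondrocyte (-0.46), proliferation (-0.16), oxidative phosphorylation (-0.09) and ribosomal protein (-0.09) lists fell, and immediate early (0.42), NF-kB (0.30), regulatory T cell (0.27), T cell (0.17) and pro-B (0.16) lists rose. Their adjusted p lay between 2.94e-07 and 0.0366, and their adjusted p between 0.593 and 0.922 with an estimated correlation. The edgeR count of called genes was 0, with 570 at an unadjusted p under 0.05, DESeq2 called 1 higher and 4 lower, voom 0, and 13.9% of genes had separate ranges where chance gives 10%. The 16 called lists became 9 without CaP week 2 replicate 1, and 5 calls held with each library left out in turn: osteoblast, matrix, muscle, erythroid and immediate early. The chondrocyte value depends on CaP week 6 replicate 3: without it the median was -4.87 (adjusted p = 5.57e-12), and without replicates 1 and 2 of that week it was 0.13 and 0.12 (adjusted p = 0.400 and 0.476). The osteoblast list was then at -1.25, -0.32 and -0.36. The chondrocyte call also ended without CaP week 2 replicate 3 (adjusted p = 0.262). Without CaP week 2 replicate 1 the interferon and NF-kB calls ended at -0.11 and 0.06 (both adjusted p = 0.392), and without week 2 replicate 3 the endothelial and osteocyte calls ended at -0.31 and -0.54 (adjusted p = 0.352 and 0.0856).

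Within PCL, week 6 against week 2, the regulatory T cell and Th2 list rose by a median of 0.60 with 9 of 9 members above 0 (camera adjusted p = 6.19e-06; adjusted p = 0.187 with an estimated correlation). Foxp3 stood at 3.87 ± 0.584 after 0.921 ± 0.205 CPM, a difference of 2.07 ± 0.31 (edgeR adjusted p = 0.0938; 0.031 without PCL week 6 replicate 1). The NK list rose by 0.72 (adjusted p = 6.52e-06; adjusted p = 0.246 with an estimated correlation), with Gzma, a cytotoxic protease, at 2.42 ± 0.738 after 0.410 ± 0.133, and the T cell list by 0.39 (adjusted p = 7.86e-05; adjusted p = 0.846 with an estimated correlation). The Schwann list rose by 0.86 (adjusted p = 0.000438; adjusted p = 0.837 with an estimated correlation), with Mbp, a myelin protein, at 57.2 ± 17.3 after 35.0 ± 0.637. The osteoblast list fell by 0.97 (adjusted p = 1.46e-06; adjusted p = 0.627 with an estimated correlation). The matrix list fell by 0.87 with 18 of 18 members below 0 and muscle rose by 1.17 with 16 of 16 members above 0 (both adjusted p = 6.52e-06; both adjusted p = 0.846 with an estimated correlation). Col1a1 stood at 8305 ± 1567 after 18847 ± 4358.

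NF-kB targets rose around PCL by 0.66 in 16 of 16 (adjusted p = 0.000281; adjusted p = 0.846 with an estimated correlation). M1-type (0.46), M2-type (0.36) and MHC class II (0.44) lists rose with adjusted p from 0.022 to 0.0356. Without PCL week 6 replicate 1 these 3 calls ended (adjusted p of 0.286, 0.351 and 0.256). Proliferation (-0.21), interferon (-0.24) and oxidative phosphorylation (-0.11) lists fell with adjusted p from 0.000203 to 0.019. With an estimated correlation the adjusted p of these 6 lists lay between 0.846 and 0.856. By gene, edgeR called 0, with 1166 at an unadjusted p under 0.05; DESeq2 called 14 higher and 15 lower, voom 1059 and 686, and edgeR 52 without PCL week 6 replicate 1. Of the 14 list calls, 9 held with each library left out in turn, among them regulatory T cell, NK, T cell, Schwann, osteoblast, matrix, muscle and NF-kB. Without PCL week 2 replicate 2 the regulatory T cell and T cell lists were at 0.95 and 0.74, without week 2 replicate 3 the matrix list was at -0.51, and the interferon call ended without week 2 replicate 1 at 0.02 (adjusted p = 0.760). Ranges were separate for 14.5% of genes, where chance gives 10%.

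Whether a scaffold difference changed between the weeks was tested as an interaction, positive where the difference was higher at week 6. For ACPC-NP against PCL the M1-type list fell by 3.43 at the median (camera adjusted p = 7.09e-09; adjusted p = 0.298 with an estimated correlation), NF-kB targets fell by 2.29 with 16 of 16 members below 0 (adjusted p = 5.53e-10; adjusted p = 0.384 with an estimated correlation) and the M2-type list fell by 1.46 (adjusted p = 1.26e-07; adjusted p = 0.298 with an estimated correlation). Ccl4, a macrophage chemokine, differed by -5.95 ± 1.12 and Foxp3 by -2.40 ± 0.43. Hypoxia (-1.25), immediate early (-1.43), regulatory T cell (-1.41), MHC class II (-1.18), NK (-0.59), T cell (-0.57) and BMP and TGF-beta (-0.39) lists also fell, with adjusted p from 6.8e-07 to 0.00635, and adjusted p from 0.298 to 0.581 with an estimated correlation. The erythroid list rose by 1.00 with 14 of 15 above 0 (adjusted p = 1.1e-08; adjusted p = 0.298 with an estimated correlation), with Car1 at 1.49 ± 0.51 and Hbb-b1 at 1.03 ± 0.33. Muscle (1.31), eosinophil (1.00), granulocyte progenitor (0.97), neutrophil (0.79), haematopoietic progenitor (0.63), proliferation (0.46), oxidative phosphorylation (0.13) and ribosomal protein (0.10) lists rose, with adjusted p from 1.1e-08 to 0.0228, and adjusted p from 0.298 to 0.817 with an estimated correlation. With 1768 genes at an unadjusted p under 0.05, edgeR called 0, DESeq2 called 132 and voom 1953. The edgeR count was 148 without ACPC-NP week 2 replicate 1 and 62 without PCL week 6 replicate 1. Without ACPC-NP week 2 replicate 3 the M1-type, NF-kB, hypoxia, immediate early, MHC class II and T cell lists were at -1.39, -0.79, -0.28, -0.51, -0.68 and -0.31, the proliferation list was at 0.21 and Ccl4 at -4.17, and all 19 lists stayed called. The muscle list turned to -0.41 without ACPC-NP week 6 replicate 3 and its call ended (adjusted p = 0.566). Of the 19 calls, 14 held with each library left out in turn, not those of muscle, oxidative phosphorylation, ribosomal protein, T cell and NK lists.

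For ACPC-NP against CaP the interaction was 1.18 for the erythroid list, which rose with 14 of 15 members above 0 (camera adjusted p = 3.85e-13; adjusted p = 0.393 with an estimated correlation), 12 of them adjusted over the list alone. Alas2 differed by 1.28 ± 0.36 and Epb42, a red cell membrane protein, by 1.27 ± 0.35. The immediate early list fell by 1.80 with 21 of 21 members below 0 (adjusted p = 9.81e-12; adjusted p = 0.393 with an estimated correlation), with Hspa1b at -6.07 ± 1.29. The osteoclast list fell by 0.96 (adjusted p = 0.00149; adjusted p = 0.393 with an estimated correlation), with Acp5 at -1.31 ± 0.41 and Nfatc1 at -0.62 ± 0.17, while Car2, carbonic anhydrase 2, went the other way at 1.22 ± 0.36. M1-type (-2.32), NF-kB (-1.79), hypoxia (-1.45), M2-type (-1.43), regulatory T cell (-0.93), MHC class II (-0.57), pro-B (-0.47) and BMP and TGF-beta (-0.32) lists fell, with adjusted p from 1.42e-08 to 0.0345, and adjusted p from 0.393 to 0.764 with an estimated correlation. Muscle (1.13), granulocyte progenitor (1.13), adipocyte (0.75), haematopoietic progenitor (0.70), eosinophil (0.68), neutrophil (0.63), proliferation (0.47) and ribosomal protein (0.19) lists rose, with adjusted p from 5.48e-06 to 0.0419, and adjusted p from 0.393 to 0.839 with an estimated correlation. Pparg differed by 1.26 ± 0.30. Of genes, edgeR called 0 with 1673 at an unadjusted p under 0.05, DESeq2 183 and voom 169; edgeR called 57 without ACPC-NP week 2 replicate 1 and 1 without replicate 2. Without ACPC-NP week 2 replicate 3 the immediate early, osteoclast, M1-type, NF-kB, hypoxia and M2-type lists stayed called at -0.74, -0.51, -0.60, -0.66, -0.44 and -0.54 and proliferation at 0.16, Hspa1b was at -3.77, and the MHC class II call ended at -0.17 (adjusted p = 0.117). Without ACPC-NP week 6 replicate 3 the muscle list turned to -0.57 (adjusted p = 0.169), and the adipocyte and pro-B calls ended (adjusted p of 0.0783 and 0.0558). Of the 19 calls, 12 held with each library left out in turn, not those of muscle, adipocyte, neutrophil, pro-B, regulatory T cell, MHC class II and BMP lists. The neutrophil call ended without ACPC-NP week 2 replicate 1 (adjusted p = 0.344) and the BMP call without CaP week 2 replicate 1 (adjusted p = 0.225).

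For CaP against PCL the interaction was negative for endothelial (-0.74), M1-type (-0.57), NK (-0.52), Schwann (-0.44), erythroid (-0.28) and regulatory T cell (-0.21) lists, which fell, and positive for immediate early (0.15), neutrophil (0.13) and pro-B (0.11) lists, which rose. Their adjusted p lay between 0.00484 and 0.0269, and was 0.926 for each with an estimated correlation. Wnt5a differed by 2.96 ± 0.84, Foxp3 by -1.79 ± 0.42 and Nxph4 by 2.47 ± 0.50. Genes called by edgeR were 0, with 198 at an unadjusted p under 0.05, DESeq2 2 and voom 0. The edgeR count was 1 without PCL week 6 replicate 1, and the 9 called lists became 14 without PCL week 6 replicate 2. Only the Schwann cell call held with each library left out in turn. Without PCL week 2 replicate 2 the erythroid and immediate early calls ended at -0.04 and -0.11 (adjusted p = 0.891 and 0.289), and without CaP week 2 replicates 2 and 3 the NK and endothelial calls ended at -0.18 and -0.36 (adjusted p = 0.160 and 0.217).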

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

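The interaction tests and the other splits of the libraries were planned, while the tests of explanations for the 3 patterns below, and the comparison of ACPC-NP with the mean of CaP and PCL, were chosen only after the result was seen. The lists named first stand here because the difference between scaffolds changed between weeks 2 and 6 in the interaction test. Between ACPC-NP and PCL the change was -3.43 for the M1-type macrophage list and -1.46 for the M2-type list. For the regulatory T cell and Th2 list it was -1.41. Differences seen at week 2 were lower at week 6, partly as all 3 lists rose over time around PCL (Foxp3 by 2.07 ± 0.31). Without ACPC-NP week 2 replicate 3 the changes were -1.39, -1.10 and -1.12, and all 3 stayed called. In the same comparison it was 1.00 for the erythroid list and 0.63 for the haematopoietic progenitor list. Between ACPC-NP and CaP it was 1.18 for the erythroid list and 0.70 for the haematopoietic progenitor list. The numbers of lists called in these interactions were 19 and 19, and 9 for CaP against PCL. Other splits of the libraries reached 27, 26 and 22. As many lists came from 27, 33 and 90 of the 100 splits drawn for each, so chance is not excluded for the counts.

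The interaction tests by edgeR called 0 genes (unadjusted p under 0.05 for 1768, 1673 and 198; DESeq2 132, 183 and 2; voom 1953, 169 and 0), and all 100 splits gave as many. The highest other splits called 1004, 64 and 1, and the split with 1004 set ACPC-NP week 6 replicates 1, 2 and 3 with ACPC-NP week 2 replicate 1 and PCL week 2 replicates 1 and 3, which points to a structure of the samples. Since that split keeps the 3 ACPC-NP libraries of week 6 together, it does not show a structure apart from the scaffold, and its source was not tested. For ACPC-NP against the mean of CaP and PCL at week 2, 590 genes were called, the highest other split had 697, and 3 of 84 splits gave as many. That comparison was chosen after seeing the data and the count was 10 without ACPC-NP replicate 3, so chance is not taken as excluded for it. For lists at week 2 (17 called, highest other 24, 29 of 84 splits) and at week 6 (14 called, highest other 22, 48 of 84 splits) chance is not excluded. At week 6 edgeR called 0 genes in the pooled comparison, with 2421 at an unadjusted p under 0.05, 623 by DESeq2 and 3466 by voom. All 84 splits gave as many, and the highest other split called 817, with CaP replicate 3 and PCL replicates 2 and 3 set against the rest, a structure whose source was not tested either.

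With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The counts of lists in the real split and the highest other were 19 and 21 for ACPC-NP against PCL at week 2, 15 and 21 for ACPC-NP against CaP, and 8 and 19 for CaP against PCL. At week 6 they were 11 and 18, 18 and 19, and 5 and 21 in the same order. From week 2 to week 6 they were 21 and 21 for ACPC-NP, 16 and 21 for CaP and 14 and 16 for PCL. Splits with as many lists numbered 3, 8, 10, 8, 5, 10, 3, 5 and 5 of 10. For genes the real count by edgeR was 0 and the highest other 0, except that ACPC-NP against PCL at week 6 had 288 in another split, CaP against PCL at week 6 had 1, and ACPC-NP over time had 1 in the real split and 1 in another, 2 of 10 in all. The split with 288 set PCL week 6 replicate 1 with ACPC-NP replicates 1 and 2.

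The osteoclast, macrophage and hypoxia lists were higher around ACPC-NP at week 2. This may come from replicate 3 alone, stress during tissue digestion, chance differences between libraries or a response to the nanoparticles. The tables argue against replicate 3 alone for the osteoclast and M2-type lists. On both, 3 of 3 ACPC-NP libraries scored above all 6 CaP and PCL libraries of that week, replicates 1 and 2 by at least 0.390 and 0.401, beside an SD of 0.119 and 0.228 over the 6. They also argue against digestion stress for these 2 lists, since replicates 1 and 2 had immediate early scores in the range of the 6 (-0.717 to 0.207). On the hypoxia and monocyte lists 3 of 3 also scored above all 6, but by as little as 0.114 and 0.0626, within the SD of 0.190 and 0.149, so both explanations stay open. Both stayed called without replicate 3 (camera adjusted p = 1.28e-11 and 0.00161; adjusted p = 0.370 and 0.631 with an estimated correlation). The bound was chosen after the scores were seen and decides the hypoxia list: its replicates 1 and 2 averaged 3.11 standard errors above the 6, and the lower lay 3.07 prediction SDs above the line on immediate early scores (2.68 and 1.33 for monocytes). On the M1-type list replicate 2 (1.21) passed the highest of the 6 (0.103). Replicate 1 differed from the highest by -0.128, so replicate 3 alone stays open. Replicate 3 did carry the size of the NF-kB target and hypoxia differences, 0.15 and 0.37 at the median without it, and the proliferation call, which ended without it (camera adjusted p = 0.142). The osteoclast, M2-type, monocyte and M1-type medians were then 0.47, 0.46, 0.50 and 0.74. For NF-kB target and M1-type lists digestion stress and a tissue response cannot be told apart. The library highest on both was highest on immediate early genes, at 1.97. A response to the nanoparticles stays open and was not tested.

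The erythroid list was higher and the B cell list lower around ACPC-NP at week 6. PCL week 6 replicate 1 alone is argued against for the erythroid list, whose difference from PCL was 0.78 without it and 0.74 with it. More red cells left after the lysis step could raise erythroid genes such as Hbb, at 50186 ± 7982 CPM, and would lower B and T cell genes alike. For the B cell list the size of the median argues against red cells, but library scores do not. The erythroid list took 6.94% of counts around ACPC-NP and 4.14% around the others, which by itself changes all other genes by -0.04 on the log2 scale. The B cell median was -0.55 in the pooled comparison, -0.51 from that change, beside an SD of 0.371 over members, not libraries. The neutrophil, granulocyte progenitor, pro-B and T cell medians were 0.49, 0.52, -0.50 and 0.02. Camera adjusted p of the B cell, pro-B, neutrophil and granulocyte progenitor lists was 0.000519, 0.000791, 5.16e-05 and 0.00467, and adjusted p was 0.816, 0.814, 0.814 and 0.816 with an estimated correlation. Chance is not excluded for these differences, since the neutrophil minus B cell score was 0.97 higher around ACPC-NP, as large in 6 of 84 splits, and PCL replicate 1, at 0.717, lay above the lowest ACPC-NP library at 0.243. The B minus T cell score differed from the 6 others by -0.40 on average, but libraries overlapped, as red cells alone predict. The lowest ACPC-NP haematopoietic progenitor score minus the highest other was -0.17. For the erythroid list incomplete lysis and a change of the marrow cells cannot be told apart, because leftover red cells would raise it by themselves. An effect of the scaffold stays open as untested.

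The skeletal muscle list was higher at week 6 than at week 2 around each scaffold. ACPC-NP week 6 replicate 3, with a score of 2.84, is argued against as the only source, since the larger camera adjusted p of CaP and PCL was 6.52e-06 (adjusted p = 0.593 and 0.846 with an estimated correlation). The scores did not overlap between the weeks in either: the lowest of week 6 and highest of week 2 were -0.546 and -0.638 for CaP and 0.216 and -0.107 for PCL. All 48 of 48 member differences over the 3 scaffolds were above 0. Adjoining muscle taken with the bone and regrowth of muscle between the weeks both predict this, so they cannot be told apart. Its most abundant gene, Acta1, skeletal actin, stood at 68.3 ± 23.5 CPM around PCL at week 6 and 31.2 ± 8.25 at week 2, and all 16 members were measured in these libraries at both weeks.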

How the results depend on the processing

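Chosen after seeing the data were the pooled comparison, voom without ACPC-NP week 2 replicate 3 and the shared spread without that library. The other settings were planned. Of the 785 gene and comparison pairs named, all kept direction and side of the threshold with the size factors of DESeq2 in edgeR and without the low-count filter. DESeq2 called 271 of them that the main test did not and left 513 as they were, and voom called 286, left 482 and moved 17. Voom without ACPC-NP week 2 replicate 3 called 132, left 636 and moved 17. The shared spread without that library left all 407 that it covers. With only the groups compared 777 stayed, 1 gained and 1 lost its call. With the replicate block 762 stayed, 16 gained a call, 1 lost it and 6 uncalled ones changed sign. Of 5694 fits with 1 library left out, 5291 stayed, 294 gained a call, 4 lost it (Gal over time in ACPC-NP) and 105 uncalled ones changed sign. Of the counts of genes and lists, all 24 under the size factors of DESeq2 and all 12 without the filter stayed within 1.5 times. No call of a named gene reversed. Of 174 list calls, 88 held with each library left out in turn, and 1 was called in the opposite direction: the skeletal muscle list for ACPC-NP against CaP at week 6, at 1.06 (camera adjusted p = 0.00799) and at -0.68 (0.0123) without ACPC-NP week 6 replicate 3. With 3 libraries per group, whether spread between libraries or depth limits the calls was not tested. The cause of each change below was not tested unless stated.

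DESeq2 called 632 genes for ACPC-NP against PCL and 595 against CaP at week 2, 878 and 23 at week 6, 792, 5 and 29 over time in ACPC-NP, CaP and PCL, and 132, 183 and 2 in the interactions of ACPC-NP with PCL, ACPC-NP with CaP and CaP with PCL. For ACPC-NP against the mean of CaP and PCL it called 1013 at week 2 and 623 at week 6. The corresponding counts by voom with quality weights were 309 and 376 at week 2, 4056 and 71 at week 6, 1387 over time in ACPC-NP and 1745 in PCL, 1953 and 169 in the interactions with PCL and CaP, and 889 and 3466 for the mean of CaP and PCL at weeks 2 and 6. Voom without ACPC-NP week 2 replicate 3 called 3988 for ACPC-NP against PCL and 10 against CaP at week 6, 121 over time in ACPC-NP, 1599 in PCL and 532 in the interaction with PCL. These counts stand against 0 by edgeR, 1 over time in ACPC-NP and 590 for the pooled comparison at week 2.

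With only the groups compared edgeR called 1 gene for ACPC-NP against CaP at week 6 and 0 over time in ACPC-NP. With a correlation estimated for each list in place of 0.01, camera called 0 lists in each of the 12 comparisons. The shared spread without ACPC-NP week 2 replicate 3 gave 10 lists for CaP against PCL at week 6 where all libraries gave 5.

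With the replicate block edgeR called 427 genes for ACPC-NP against PCL at week 6, 1 over time in PCL and 0 over time in ACPC-NP, and the other 21 counts stayed within 1.5 times. Pairing by replicate number within a week is not excluded. Between scaffolds, mean correlations ran from -0.130 to 0.205 for the same number and from -0.103 to 0.0645 for other numbers. Over time the lowest was -0.303, and 8 of 18 libraries correlated best with their own number.

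With each library left out in turn, counts of genes by edgeR ran from 0 to 877 for ACPC-NP against PCL and from 0 to 893 against CaP at week 2, each highest without ACPC-NP replicate 1 and 0 without replicate 3. They ran from 0 to 1787 for ACPC-NP against PCL at week 6, 0 to 1 for CaP against PCL at week 6, 0 to 52 over time in PCL, and 0 to 1 in the interaction of CaP and PCL, each highest without PCL week 6 replicate 1. The range was 0 to 882 over time in ACPC-NP, 0 to 148 in the interaction with PCL and 0 to 57 in that with CaP, each highest without ACPC-NP week 2 replicate 1. For the mean of CaP and PCL it was 10 to 1363 at week 2, lowest without ACPC-NP replicate 3 and highest without replicate 1, and 0 to 1335 at week 6, highest without PCL replicate 1. Counts of lists ran from 10 to 18 for ACPC-NP against PCL at week 6 (highest without ACPC-NP replicate 3), 6 to 13 for CaP against PCL at week 2 (CaP replicate 1 or PCL replicate 2), 7 to 12 at week 6 (PCL replicate 1), 7 to 14 in their interaction (PCL week 6 replicate 2) and 9 to 17 over time in CaP (lowest without CaP week 2 replicate 1). Every left-out fit leaves 2 libraries in a group, whose spread is taken as that of the other groups.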

Other observations

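Among genes outside the called lists of week 2, Sdc1, a surface proteoglycan of plasma cells and epithelia, stood at 485 ± 560 CPM around ACPC-NP against 29.1 ± 8.31 around PCL, a log2 difference of 4.06 ± 0.78 (n = 3 each; edgeR adjusted p = 0.0712) that was 2.47 without ACPC-NP replicate 3 (adjusted p = 0.297). Pf4, a chemokine of platelets and macrophages, stood at 115 ± 85.6 against 25.3 ± 6.06, and Pdpn, a membrane protein of early osteocytes, at 352 ± 484 against 10.4 ± 1.98. Without that library Pf4 differed by 1.38 and Pdpn by 2.84 (adjusted p of 0.164 and 0.181). Their lists were not called: plasma cell, megakaryocyte and osteocyte medians were -0.04, -0.10 and -0.01 while the means were 0.47, 0.60 and 0.70. Wnt10b stood at 3.74 ± 0.890 around ACPC-NP against 7.32 ± 2.07 around PCL and 6.21 ± 0.809 around CaP at week 2, with no overlap of libraries and without a call (adjusted p of 0.155 and 0.285). Mmp13, a collagenase, differed from PCL by 1.69 ± 0.65 and from CaP by 0.93 ± 0.64.

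Cartilage genes varied widely between libraries of the same group. Col2a1, the main collagen of cartilage, ran from 11.8 CPM in ACPC-NP week 6 replicate 1 to 7318 in PCL week 2 replicate 2. The chondrocyte score averaged 1.36 ± 0.580 around CaP, 0.489 ± 0.589 around ACPC-NP and 0.367 ± 2.50 around PCL at week 2 (SD, n = 3 each). In ACPC-NP against the mean of CaP and PCL at week 6, a comparison chosen after seeing the data, the erythroid list rose by 0.65 at the median (camera adjusted p = 7.24e-08; adjusted p = 0.814 with an estimated correlation) and the neutrophil list by 0.49 (adjusted p = 5.16e-05; adjusted p = 0.814 with an estimated correlation). EdgeR called 0 genes there. Without PCL week 6 replicate 1 edgeR called 1335, and without CaP week 6 replicate 3 it called 1. Ranges were separate for 14.7% of genes, where chance gives 2.38%.

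Some abundant genes are nearly missing from the deposited counts. Col1a2 had 1 to 14 counts per library where Col1a1 had 102355 to 643110. Ribosomal genes Rps9, Rpl7a and Rps19 had 0 to 6, 0 to 5 and 2 to 13 counts. Values of these genes are not interpreted here.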
